A study of Bos taurus with 10 samples.

How the data were processed

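Endometrium, the lining of the uterus, was sampled from 10 Simmental cattle on day 18, as 5 monozygotic twin pairs made by embryo splitting. In each pair 1 twin had received in vitro produced embryos and carried a conceptus, and the other had received a sham transfer and served as a cycling control. Groups were taken from the source labels. The series design names the twin pairs as the unit of comparison, and partners were identified from consecutive animal numbers and equal ages. Labelled cDNA, carrying the radioisotope 33P and made from total RNA, was hybridised to a set of 3 arrays holding PCR products of 4608 clones from subtracted cDNA libraries. The libraries had been enriched for transcripts more abundant in the pregnant twin of pair 4. Per the labels, 1 array of pair 4 (array B) gave weak signals and was left out by the authors. In the table both animals of that pair lack values for 1536 clones on 16 plates, and the pregnant animal lacks 1 further value.

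The deposited values are intensities on a linear scale, 1 per clone and sample, never below 0. The image analysis software, background correction and normalisation are not given in the sources used here, and no signal of empty spots was used here. The sample medians ranged over 1.7 on the log2 scale, a 3.26-fold range, so the deposited intensities were not equalised on the median. The number of arrays limits the precision.

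Clones are known here only by prefix, plate and well. The files do not pair clones with genes, and none of the identifiers could be matched to the RefSeq gene table of cattle (assembly ARS-UCD2.0), so 0 gene names were assigned. The planned gene-level fit and the tests of gene lists were therefore not computed. Following the rule for unnamed clones, the text names the 2 clones with the largest rise and the 2 with the largest fall among clones past the threshold that moved the same way in every pair. Clones of the same cDNA can occur several times, so clones are not independent of one another.

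The 3 clone prefixes are 18c, 18e and 18f. Array B was taken to be the 16 plates without values in pair 4, and the split of the other plates over the arrays was inferred from plate names.

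Each sample was divided by the ratio of its median to the geometric mean of all sample medians, which gave all samples a common median. Values below the 5th percentile of all positive values (0.116 after scaling) were set to that floor, and log2 was taken. This centring follows a rule fixed before the data were examined, which applied it where sample medians differed by more than 0.5 on the log2 scale. Between 1.06% and 8.57% of values per sample lay at the floor. Differences between pregnant and control twins were tested per clone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 3.34) with the twin pair as a block. Clones with both values in at least 3 pairs were tested, which kept all 4608, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Because the centring moved the differences by a median of 0.58 on the log2 scale, the same fit on the values as deposited is given beside it. The selection rule in the series design, a ratio of at least 2 in at least 4 pairs, was counted in both directions. Shares of clones by prefix carry exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared by two-sided Fisher's exact tests. The comparisons of prefixes and plates and the held-out pairs were added after the data had been seen.

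The fit was tested on simulated data with the real clone and pair means and residual spread, 4608 clones, 100 clones changed by 1 and 100 changed by 2 on the log2 scale. It recovered 22% of the former and 76% of the latter, and 5.77% of its 104 calls were false. The changes were added to values already centred, as many up as down, so the effect of the scaling on the calls was not simulated. Far more clones were called in the real data than were changed here, so these shares need not apply to the real calls. The pairing was checked on the deviations from the group means over 3071 clones. Twins correlated with r between 0.334 and 0.733, and all 10 samples had their own twin as the best match in the other group, so the pair was kept as a block.

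The control animal of pair 2 is titled and sourced as a control, but its treatment text repeats that of its pregnant twin, progesterone level included. It was analysed as a control, its progesterone level was treated as unknown, and counts without pair 2 are given. Alternatives were the fit without the block, values as deposited, quantile normalisation, centring of each array, other filters and floors, other moderation, other fold limits and leaving out each twin pair. The image figures were drawn with matplotlib 3.10.9.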

Results

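The comparison asked which transcripts of the endometrium differed between pregnant and cycling animals on day 18, before the embryo attaches, with the genetic background held equal by the use of identical twins. Intensities of 4608 cDNA clones were measured in 5 pregnant animals and their 5 control twins, and 3071 of the clones had values in both twins of pair 4. Median intensities were 1.89, 2.8, 1.68, 1.36 and 1.63 in the pregnant animals of pairs 1 to 5, and 1.35, 1.95, 0.92, 0.86 and 1.29 in their control twins. The brightest clone of each sample reached between 407 and 1042. The animals are separate individuals. Below, SDs of group means measure the spread between animals of a group, and SDs of differences the spread between twin pairs. SEs are those of the moderated fit, which also draws on the spread of other clones.

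A large set of clones was more abundant in pregnant endometrium. After centring, 530 of the 4608 clones (11.5%) were higher in the pregnant twins, with a median rise of 2.06 on the log2 scale. All 530 were also called higher on the values as deposited, where the count was 731. Each pregnant sample had a higher median than its control twin, so centring lowered the differences in every pair, which favours this overlap. Of the 530 clones, 474 rose at least 2-fold, 275 at least 4-fold, 142 at least 8-fold, 65 at least 16-fold and 33 at least 32-fold. In 507 of them the pregnant twin was higher in every pair measured, which the call on these same pairs favours. These calls used limma with the pair as a block and an adjusted p threshold of 0.05. A single risen clone had every control value at the floor, so its fold is a lower bound. Without pair 5 the count of higher clones was 350, and without any of the other pairs it lay between 355 and 462.

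The number of clones lower in pregnant endometrium depended on the scaling, and their median change was smaller than that of higher clones. After centring, 732 clones (15.9%) were lower in the pregnant twins, with a median difference of -0.93. On the values as deposited 36 clones (0.781%) were lower, and all 36 were among the 732, which the downward shift by centring favours. The share of calls that were higher was thus 42% after centring and 95.3% as deposited. Of the 732 clones, 284 fell at least 2-fold, 7 at least 4-fold and 0 at least 8-fold. As deposited, 23 fell at least 2-fold and 1 at least 4-fold. The median difference of all clones was -0.33 after centring and 0.19 as deposited. Without pair 3 the count of lower clones was 78, without pair 2 it was 191, without pair 5 it was 233, without pair 1 it was 258 and without pair 4 it was 544. On the values as deposited these counts lay between 13 and 32. Here too the counts without pair 4 are not directly comparable with the others. Without the pair block, limma called 294 clones higher and 13 lower.

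**Figure D1:**
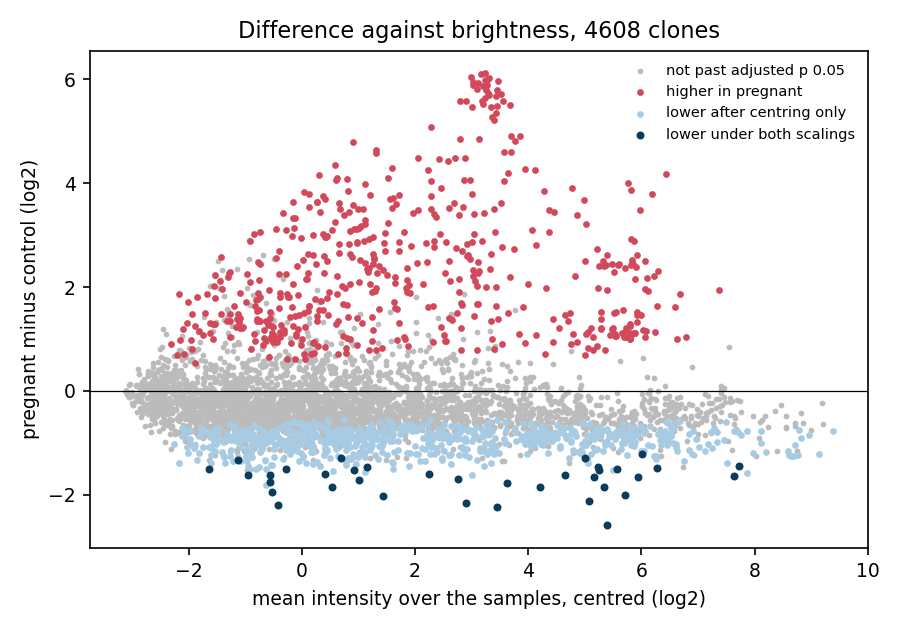
Difference between pregnant and control twins (log2, y axis) against mean intensity over the samples (log2 after centring, x axis), 1 point per clone, coloured by the limma call at an adjusted p of 0.05. The 530 higher clones reach a rise of 6.11 and include a compact group above 5, while the 36 clones that were lower under both scalings lie at or above -2.58.

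Intensities of named clones are given as deposited, while their log2 differences, SEs and folds are after centring unless stated otherwise. The clone with the largest rise, 18f-02-B04, had an intensity of 102 ± 36.6 (SD, n = 5) in pregnant and 1.05 ± 0.559 (SD, n = 5) in control animals. Its log2 difference was 6.11 (SE 0.207), a 69.3-fold rise, and ranged from 5.63 to 6.44 over the pairs (limma, adjusted p = 1.09e-05). The next clone, 18e-01-D03, had 95.5 ± 34.5 (SD, n = 5) in pregnant and 1.09 ± 0.755 (SD, n = 5) in control animals. It rose by 6.09 (SE 0.223) on the log2 scale, 68.2-fold (limma, adjusted p = 1.1e-05). As deposited, these differences were 6.69 and 6.67. For 18f-02-B04 the lowest pregnant value was 60.2 and the highest control value 1.91. For 18e-01-D03 these were 51.6 and 2.31, so the groups did not overlap for either clone.

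The clone with the largest fall, 18c-07-D12, had a deposited intensity of 31.1 ± 30 (SD, n = 5) in pregnant and 125 ± 116 (SD, n = 5) in control animals. After centring it fell by 2.58 (SE 0.37) on the log2 scale, 5.99-fold, with a within-pair difference between -4.33 and -1.87 (limma, adjusted p = 0.00326). The groups overlapped, with a highest pregnant value of 79.15 and a lowest control value of 22.98, but the pregnant twin was lower in all 5 pairs. Clone 18c-19-H09, measured in 4 pairs, had deposited intensities of 6.66 ± 0.844 (SD, n = 4) in pregnant and 22.6 ± 10 (SD, n = 4) in control animals. After centring it fell by 2.23 (SE 0.297), 4.69-fold (limma, adjusted p = 0.00394). As deposited, the differences of 18c-07-D12 and 18c-19-H09 were -2.01 and -1.68, with adjusted p of 0.00404 and 0.00545 by limma.

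**Figure D2:**
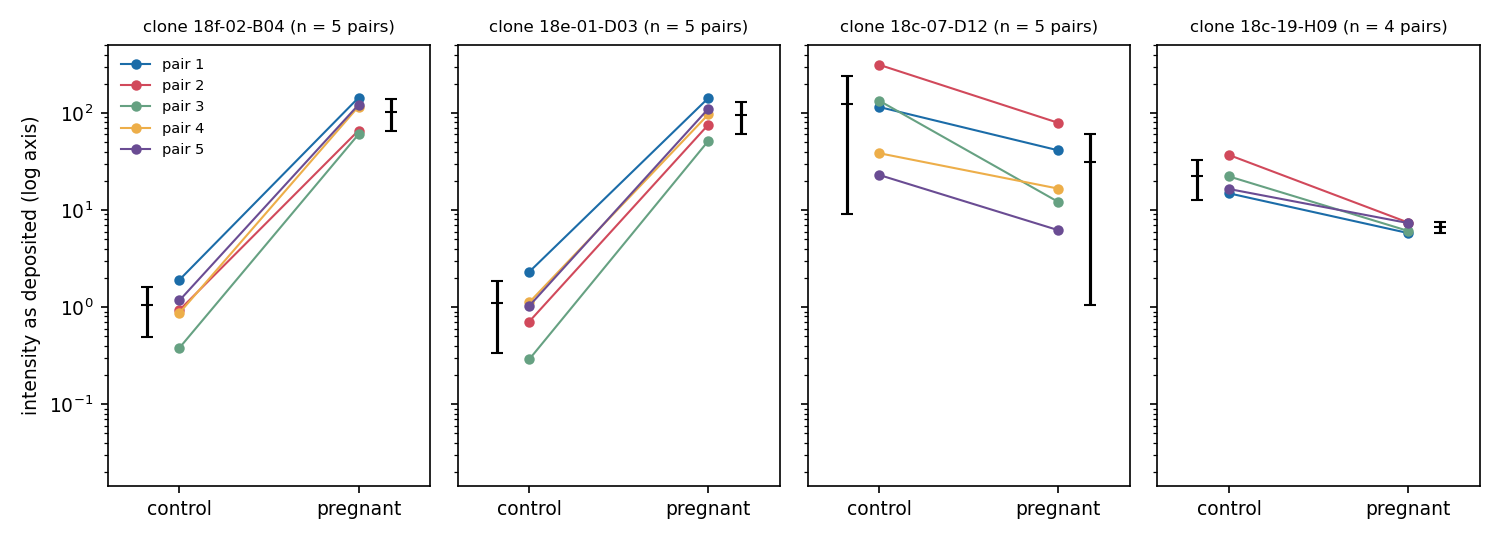
Intensity as deposited (log y axis) of the 2 clones with the largest rise and the 2 with the largest fall in control and pregnant animals, with coloured lines joining twins and black bars giving the mean ± SD. All pairs measured move the same way, and 18f-02-B04 goes from at most 1.91 in controls to at least 60.2 in pregnant animals.

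The study's own selection rule, a ratio of at least 2 in at least 4 twin pairs, was met by 361 clones (7.83%) in the direction of pregnancy after centring. All 361 were also called higher by limma. In the opposite direction 60 clones met the mirrored rule. As deposited, 538 clones met the rule and 6 met the mirrored rule. The 361 clones were all among the 538, which the shift between the scalings favours. Of the 3071 clones with values in all 5 pairs, 318 were at least 2-fold higher in every pair as deposited and 1 was at least 2-fold lower in every pair. After centring these counts were 215 and 9. Clones on array B, measured in 4 pairs, had to meet the main rule in every pair measured. With a pair left out, at least 3 pairs were required. The mirrored count was 151 without pair 1, 167 without pair 2, 78 without pair 3, 207 without pair 4 and 151 without pair 5. This requirement is looser, and the count in the direction of pregnancy also rose, to between 377 and 452. The libraries had been enriched for clones higher in the pregnant twin of pair 4, so the directions were not equally represented on the arrays, and the balance of rises and falls describes this clone set and not the endometrial transcriptome.

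The 3 clone prefixes differed in how often a clone was higher in pregnant endometrium. Clones with the prefix 18e were higher in 167 of 768 cases (21.7%, exact 95% interval 18.9% to 24.8%), 18f clones in 126 of 768 (16.4%, 13.9% to 19.2%) and 18c clones in 237 of 3072 (7.71%, 6.8% to 8.72%). The odds of a higher call were 3.32 times those of 18c for 18e (Fisher's exact test, p = 1.35e-25) and 2.35 times for 18f (Fisher's exact test, p = 4.44e-12). Between 18e and 18f the odds ratio was 1.42 (Fisher's exact test, p = 0.00931). Over the 6 such comparisons the Benjamini-Hochberg adjusted values of these 3 were 4.05e-25, 8.88e-12 and 0.00931. The labels do not say how the prefixes differ, and clones of a cDNA can recur, so these p-values, which treat clones as independent, are too small where they do. As deposited, the shares were 29.8%, 23.2% and 10.5%. The 18c clones on array B were tested on 4 pairs, and all 18e and 18f clones appear to lie on a separately hybridised array. With 18e and 18f pooled, the odds ratio over 18c was 2.82 in the main fit. It was 2.32 with all 5 pairs required and 1.88 with each array centred on its own median.

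Clones on plates marked VS were higher more often than those on other plates, with an odds ratio of 1.79 (Fisher's exact test, p = 4.9e-06, adjusted 7.35e-06), and the labels do not explain the mark. VS plates are more frequent among 18e and 18f plates than among 18c plates, so this ratio includes the difference between prefixes. Within prefixes the shares on VS and other plates were 8.85% and 7.64% for 18c, 22.9% and 21.4% for 18e, and 20.8% and 14.9% for 18f, with overlapping exact 95% intervals. As deposited they were 10.4% and 10.6% for 18c, 29.2% and 30% for 18e, and 29.2% and 21.2% for 18f. The order thus turned for 18c and 18e and held for 18f. Overlap of intervals is not a test, so a difference within 18f is not excluded. Among 18c clones, those on array B were higher in 96 cases (6.25%) and the others in 141 (9.18%), an odds ratio of 0.66 (Fisher's exact test, p = 0.00286, adjusted 0.00343). Array B lacked pair 4, so its clones were tested on 4 pairs. Lower calls went the other way, with 296 (19.3%) on array B and 265 (17.3%) among the other 18c clones. As deposited the lower calls were 19 and 12. The cause of these differences was not tested. For 18e and 18f clones pooled against 18c clones the odds ratio was 2.82 (Fisher's exact test, p = 2.01e-28, adjusted 1.21e-27). The single plates spanned 15.6% to 27.1% higher clones for 18e, 10.4% to 25% for 18f and 2.08% to 12.5% for 18c.

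The share of lower clones followed another order. After centring it was 18.3% for 18c, 16.7% for 18f and 5.6% for 18e. As deposited it was 1.01%, 0.651% and 0%, the last being 0 of 768 clones by limma, with 6 at an unadjusted p under 0.05. The median rise among higher clones was 2.02 for 18c, 1.89 for 18e and 2.34 for 18f, with overlapping interquartile ranges. The largest rises were unevenly spread: of the 33 clones above 5 on the log2 scale, 27 were 18e clones, 6 were 18f clones and 0 were 18c clones, although 18c supplied 18 of the 32 clones between 4 and 5.

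**Figure D3:**
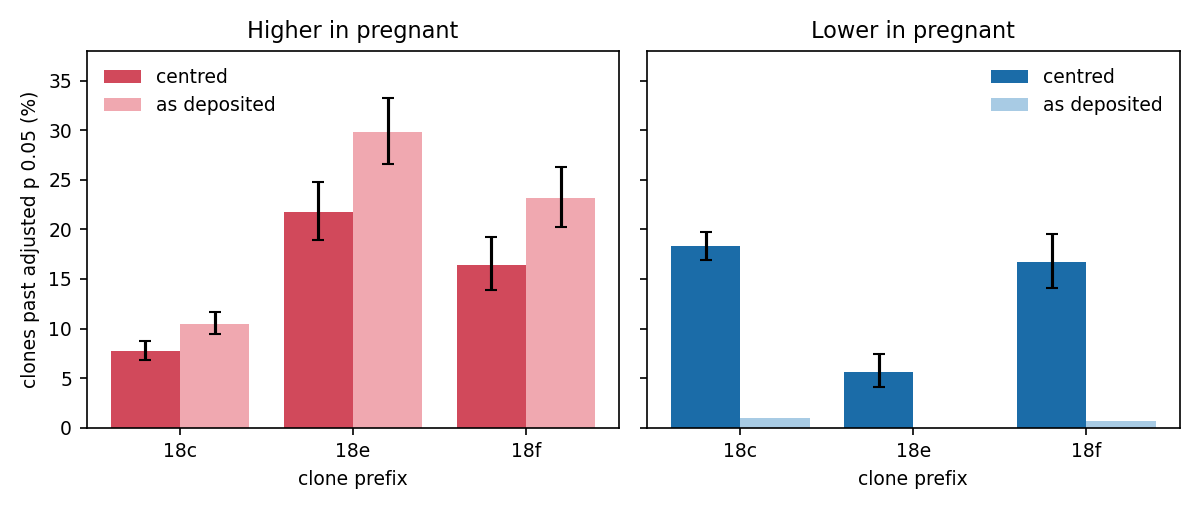
Percentage of clones called higher (left) or lower (right) in pregnant animals by clone prefix, after centring and as deposited, with exact 95% binomial intervals except for lower calls as deposited. Higher calls go from 7.71% for 18c to 21.7% for 18e after centring, and lower calls drop to between 0% and 1.01% as deposited.

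The response was shared between the twin pairs. Across clones, which are not independent replicates, the within-pair differences of any 2 pairs correlated with r between 0.575 and 0.721 (median 0.676, 10 comparisons). Each pair was also held out and the clones were called on the other 4 pairs. Of the clones called higher there, 97.8%, 94.2%, 99.2%, 96.3% and 100% were higher in held-out pairs 1 to 5 (in pair 4, of the 374 of 462 clones with values there), and 71.7% (pair 2) to 96% (pair 5) were at least 2-fold higher. Of all clones measured, between 30.5% (pair 3) and 42.3% (pair 4) were higher in the pregnant twin after centring. The clones called higher on the other 4 pairs had a median rise of 3.03 in held-out pair 5, against 2.51 in the other pairs. In held-out pair 2 the corresponding medians were 1.89 and 2.55. In pair 4, from which the libraries were made, the median rise was 2.1 against 2.29 in the other pairs. The clones were selected in those other pairs, which tends to raise the median there. This comparison therefore cannot show whether the enrichment favoured pair 4. In pair 2, which holds the control animal with the contradictory treatment text, the 2 clones with the largest rise differed by 5.63 and 6.22 between the twins.

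Of the 732 clones called lower on all pairs, 720 were lower in every pair measured after centring, which the call on these same pairs favours. Clones called lower on the other 4 pairs were lower in the held-out pair in between 81.1% (pair 4, of the 264 of 544 clones with values there) and 97.4% of cases after centring, and in between 57.2% and 87.2% on the values as deposited. Of all clones measured, between 54.4% (pair 4) and 66.3% (pair 3) were lower in the pregnant twin after centring, and between 28.4% (pair 3) and 48.4% (pair 5) as deposited. The median SD over the pairs of the within-pair difference was 0.55 for all clones, 0.66 for clones called higher and 0.43 for clones called lower. Small differences pass the threshold only where the SD is small, so the SDs of called clones partly reflect the selection.

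**Figure D4:**
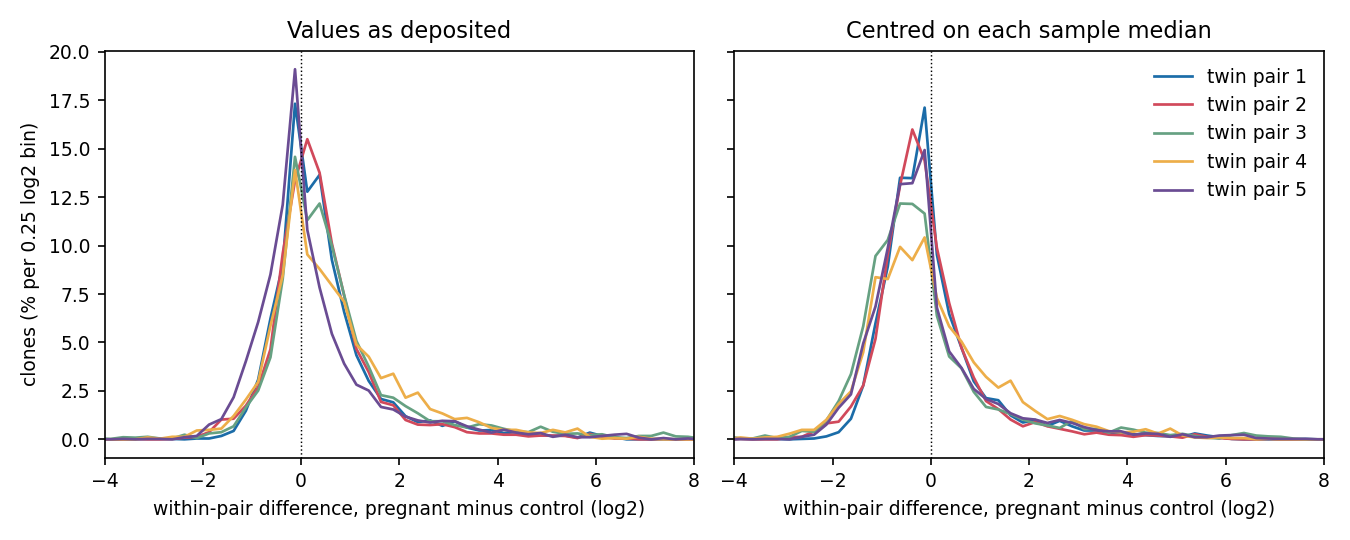
Distribution over clones of the within-pair difference (log2, x axis) in percent of clones per bin (y axis), for each twin pair, as deposited (left) and after centring (right). Among clones above the floor in both twins the most common difference lay between -0.15 and 0.26 as deposited and between -0.61 and -0.35 after centring, while clones at the floor in both twins add to the peak next to 0.

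Serum progesterone, the hormone that maintains pregnancy, was stated in the labels for 4 complete pairs. It was 4.75 ± 2.34 ng/ml (SD, n = 4) in pregnant and 3.22 ± 1.36 ng/ml (SD, n = 4) in control animals. The pregnant twin was higher in 4 of 4 pairs, by 1.52 ± 1.1 ng/ml (SD, n = 4; exact two-sided sign-flip test, p = 0.125). This is the smallest p that this test allows with 4 pairs, so the test could not reach 0.05. Without pair 3 the mean difference was 1 ng/ml.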

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

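The comparison with splits that part every twin pair was chosen after the counts of all splits were seen. Of 40 groups of 4 or 5 values examined for a value far from the rest, 3 were marked, and chance marks about 1 in 20. The mean intensity of the pregnant sample of pair 2 was 26.4, above the other pregnant samples, whose means lay between 16.05 and 19.04. Its control twin also had the highest mean of the controls, 22.47 against 10.84 to 15.62 in the others. The pregnant sample of pair 5 had 41 clones with an intensity of 0, against 1 to 11 in the other pregnant samples, and its control twin had 45. The within-pair difference of clone 18c-07-D12 was -4.33 in pair 3, against -2.51 to -1.87 in the other pairs, and without pair 3 the clone still fell, by 2.15 (limma, adjusted p = 0.00192).

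The counts of called clones were set against other splits of the 10 samples into 5 and 5, of which 100 of 126 were drawn with the real one included. Because the fit is blocked by twin pair, only the 14 drawn splits that part all 5 pairs, the real one included, compare with the real split; the others part 1 or 3 pairs. The real split called 1262 clones in either direction after centring, and the highest other of the 14 called 35. On the values as deposited the real split called 731 clones in its larger direction and the highest other 53. Under both scalings 1 of the 14 splits, the real one, reached its count, and 14 splits are too few for a share under 0.05.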

How the results depend on the processing

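Centring on the most common difference of each pair, and all alternatives for the mirrored 2-fold counts and the odds ratio over prefixes, were chosen after seeing the data. Higher clones numbered 530 and stayed between 425 and 731 under the other scalings, filters and floors and with an intensity trend in the moderation; they fell to 294 without the replicate block and 282 without moderation, and to 350 to 462 when a pair was left out (350 without pair 5). The count of lower clones followed the scaling: 732 after centring, 700 with quantile normalisation or with each array centred, 36 as deposited and 50 when centred on the most common difference. It was 13 without the replicate block, 236 without moderation, 443 with all 5 pairs required, where 3071 clones were tested, and 78 (without pair 3) to 544 (without pair 4) when a pair was left out. All 530 higher clones stayed called as deposited and when centred on the most common difference. Both settings shift the differences upward from median centring, which favours this. Without the block, 294 of the 530 stayed called. Of the 732 lower clones, 594 stayed called with quantile normalisation and 422 with each array centred. Clones 2-fold higher in at least 4 pairs numbered 361 and stayed between 256 and 538 under all alternatives run. The mirrored count of 60 became 6 as deposited, 9 when centred on the most common difference, 440 at 1.5-fold, 3 at 3-fold, 32 in every pair measured and 78 to 207 when a pair was left out and 3 pairs were required. The odds ratio of 18e and 18f over 18c, 2.82, stayed between 1.88 (each array centred) and 3.32. The balance of calls turned: 42% of calls were higher after centring, against 95.3% as deposited, 93.1% when centred on the most common difference, 95.8% without the block, 54.4% without moderation and 45.9% to 82% when a pair was left out. The median difference of all clones went from -0.33 after centring to 0.19 as deposited and 0.11 when centred on the most common difference. The 4 named clones kept their direction and call without the block, as deposited, with quantile normalisation and without each pair. Apart from the smaller number of clones or pairs tested, the cause was not tested. Leaving out pair 4 removed no pair from the clones on array B, so the results without pair 4 are not directly comparable with the others. Requiring 2 pairs removed no clone, so it tests nothing, and the gene-level and gene list alternatives were not run for want of gene names. The progesterone difference stayed between 1 and 1.83 ng/ml. Of 5 groups by mean brightness, 3.58% of clones were called higher in the dimmest and 15.3% in the brightest, and 5.21% and 27.5% lower. The median difference was -0.54 in the brightest group and between -0.34 and -0.17 in the others, and 18 of the 36 clones lower as deposited lay in the brightest; mean brightness includes the pregnant values, which a rise lifts, and no background signal was used here, so what signal limits was not tested.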

Other observations

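The tests of the lower calls, of control brightness, of the brightest 1% of clones, of the brightness of the largest rises and of their neighbours, and of plates within a prefix were chosen after their results or related ones were seen. The largest rises formed a compact group. The 33 clones that rose by more than 5 on the log2 scale had a median intensity of 90.2 in pregnant and 1.26 in control animals, and the 27 of them with the prefix 18e came from all 8 plates of that prefix. In no pair did any of them differ by less than 3.71. At the other extreme, 196 of the 3071 clones with 5 pairs (6.38%) were at least 2-fold higher in some pair and at least 2-fold lower in another as deposited, and 226 (7.36%) after centring. Just 2 clones did so with at least a 2-fold difference in all 5 pairs, 18c-01-A04 and 18c-03-E10, named after their values were seen. Both were higher in the pregnant twin in pairs 1 to 3 and lower in pairs 4 and 5. Clone 18c-01-A04 differed by 2.08, 1.24, 1.85, -2.67 and -1.8 on the log2 scale as deposited and 18c-03-E10 by 1.85, 1.23, 2.05, -2.06 and -1.2. After centring they kept these signs, but 18c-01-A04 differed by 0.72 in pair 2 and 0.98 in pair 3 and 18c-03-E10 by 0.71 in pair 2, so neither reached 2-fold in every pair.

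The brightest 1% of clones carried 22.4% ± 4.03 (SD, n = 5) of the summed intensity in pregnant and 29.4% ± 5.56 (SD, n = 5) in control samples, lower in the pregnant twin in 5 of 5 pairs (exact two-sided sign-flip test, p = 0.0625, the smallest p that this test allows with 5 pairs). On plate 18e-02, 24.5% of values lay at the floor, the highest share of the 48 plates.

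Many clones were lower after centring and few as deposited. A candidate explanation is that risen clones lift the median of a pregnant sample, so that centring lowers the difference of every clone. The most common within-pair difference as deposited averaged 0.0827 over the pairs (range -0.149 to 0.258), as this explanation needs, although the authors' scaling is unknown and could itself have set it. Of the 732 clones, 727 were already below 0 as deposited (median -0.365), so centring did not create the direction of these 727. A real fall stays open: these clones were selected for a centred fall, and with the shift of 0.58 between the scalings that selection sets both this count and the median share of the fall kept as deposited, 0.39 (interquartile range 0.295 to 0.501).

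Clones with the prefixes 18e and 18f were more often higher than 18c clones. Brightness as the whole cause is argued against, since the odds ratio was 2.56 (95% interval 2.12 to 3.09) within 5 classes of mean brightness, which a rise itself lifts, and 2.95 (2.45 to 3.56) within 5 classes of control brightness, where a low control value by chance raises the difference. So is the scaling of the separate arrays alone, with 1.88 (1.55 to 2.28) when each array was centred on its own median, and so is a single much repeated cDNA among the largest rises, with 2.5 (2.06 to 3.03) without the clones above 5. Repeats among the smaller rises and the separate hybridisation of the array that appears to hold all 18e and 18f clones stay open. The design names no biological difference between prefixes, and none was tested.

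A hypothesis for the compact group of large rises is that its clones carry the same cDNA, or very few. Their mean brightness had an SD of 0.26 on the log2 scale, 0.112 of the median SD of 10000 random sets of 33 risen clones, and the 32 clones that rose by 4 to 5 had an SD of 1.47. This describes the compact group and does not speak for a shared cDNA. Of the 33 clones, 20 (60.6%) had as nearest neighbour in the pair-to-pair profile another clone above 5, against 7.6% for random risen clones, but most share a prefix, and neighbours shared a prefix more often than random clones (46.5% against 33.6%). The hypothesis was extended to all 434 risen clones with 5 pairs, whose nearest neighbours lay at 0.973 of the distance in shuffled profiles, with 16 of 100 shuffles as close, which leaves it undecided there. Nearest neighbours shared a plate 2.51 times as often as random risen clones (95% interval 1.81 to 3.37, which treats clones as independent). When only neighbours of the same prefix were counted, the ratio was 1.87. This second ratio, which has no interval, lay below the limit set beforehand for an effect of the plate. Such an effect on the measured differences therefore stays open, and position within a plate was not tested.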
